A study of Homo sapiens with 36 samples.

How the data were processed

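The series holds 36 eCLIP libraries of K562 cells, 18 immunoprecipitated and 18 input, with 2 of each for 9 proteins. Per the labels' protocols, cells were crosslinked, lysed and sonicated, RNA was fragmented with RNase I, complexes were precipitated with a protein-specific antibody, and RNA was reverse transcribed, ligated to an adaptor and amplified. Samples were grouped by the protein and library type in their labels. Reads were handled with fastp and STAR on GRCh38, per the submitters' processing notes, which give no versions. The window caller's settings and the annotation are not given in the sources used here.

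For each protein 2 tables were used, a list of reproducibly enriched windows and a list of reproducibly enriched repeat elements. Per the file headers, the authors deposited read counts per window or element, summed over the 2 IP libraries and over the 2 input libraries. Per the file headers, enrichment is a deposited log2 odds ratio of IP over input, given as the lower, middle and higher value over replicates, and the middle value lay within 1.78e-15 of the midpoint wherever tested, which was every window and element. The deposited p-values and q-values are given as the larger and smaller of the 2 replicates. The larger q-value reached 0.200 in the window lists and 0.0499 in the element lists. The smallest p-value listed was 1e-12 for windows and 1e-10 for elements. GC content was deposited by the authors as a fraction per window and is given here as a percent. The top feature class of a window is the label in the deposited list, and the definitions of the classes are not given in the sources used here. CDS is called interior coding sequence here, windows at start and stop codons are separate classes, and labels beginning with SS were read as splice-site classes. No column held a single library, so the number of per-library columns is 0, and replicates enter only through the lower and higher values. Each list was made per protein from both replicates, so no list exists for one replicate alone. A list of windows recentred to 75 nt was not used.

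Depth per library is unknown, since the lists count reads only in called windows and listed repeat elements. Intervals on shares are 95% Wilson intervals. Whether duplicate reads were removed is not given in the sources used here. Precision differed between lists in the input, where the median window had 1 to 23 reads, in the median difference between replicates, and in the number of windows, with the longest list 196 times the shortest.

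Shares of windows by class were compared between the 4 initiation factor lists and the 5 ribosomal protein lists with two-sided exact permutation tests over all 126 splits and Benjamini-Hochberg adjustment over the 16 classes that held at least 1% of some list. The list was the unit, and no covariate was used. Small and large subunit lists (3 and 2) were set side by side. Overlap of windows with equal chromosome, start, end and strand was tested for 36 pairs with Fisher's exact test, two-sided, in the universe of windows called for at least 1 of the other 7 proteins. Odds ratios had 0.5 added to each cell, with normal intervals on the log scale. Of 22 gene lists fixed before the data were examined, 20 had at least 5 genes in the universe of 6652 genes and were tested for each protein with Fisher's exact test, adjusted over all 180 tests and over the lists of 1 protein. The 2 lists that were too short were nuclear long noncoding RNAs, with 4 genes in the universe, and markers of lymphoid, stromal and epithelial cells, with 3 of 22. Genes were taken by symbol from the lists, and older symbols were matched through a table of gene names. Repeat elements had no test of their own, and the suffix AS in an element's name was read as antisense. GC content was compared as the median over windows of a class, for lists with at least 20 windows of that class, with exact permutation tests.

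Named items followed a rule fixed with the lists. For each protein it took the 5 genes with most windows, the 5 with the highest lower-replicate enrichment in a window with at least 50 IP reads, and up to 4 members of each list that passed. It also took the 5 highest repeat elements with the ribosomal RNA, 7SL, 7SK and tRNA groups, the 10 windows called for most proteins, the stress-response mRNAs and the mRNAs of the 9 proteins. Values for a gene are those of its window with the highest lower-replicate enrichment, or, for genes with most windows, of its highest window.

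The tests were run on simulated lists. Of 360 pairs of random lists of the real lengths drawn from 57816 windows, 2 were called, and a planted overlap of RPL29 and RPS14 was recovered. Of 1800 tests on random genes out of 6652 there were 0 calls, and a planted excess of large subunit genes in the RPL35A list was found in 18 of 20 draws. Random windows and genes were drawn evenly, which is the null that the tests assume, so few calls followed by construction. The draws held no differences in expression or gene length, so they do not give the rate of false calls in the real lists. Alternatives were a larger q-value of at most 0.05, a lower-replicate log2 value of at least 1, the first 500 windows of each list, at least 20 summed input reads, genes as the unit, each protein left out, overlap of at least 1 nt, other universes and protein-coding genes alone. Restricting overlap to coding windows and leaving out the EIF2B5 list were added after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Coordinates are 1-based on GRCh38.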

Results

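RNA contacts of 9 proteins of the translation machinery were mapped in K562 cells, a human chronic myeloid leukaemia line, by enhanced crosslinking and immunoprecipitation (eCLIP). In eCLIP, proteins are crosslinked to RNA, the RNA is fragmented, one protein is precipitated with an antibody, and the RNA that comes with it is sequenced next to an input library that was not precipitated. The series compares each immunoprecipitated (IP) library with its input. Of the proteins, 4 belong to translation initiation factors. EIF2B5 is the catalytic subunit of the exchange factor for eIF2, EIF2S2 is the beta subunit of eIF2 (the factor that carries initiator tRNA to the ribosome), EIF2D can bind tRNA on the small subunit, and EIF3J is a loosely attached subunit of eIF3. The other 5 are ribosomal proteins, RPS14, RPS19 and RPS3A of the small subunit and RPL29 and RPL35A of the large subunit. The 36 libraries comprised 2 IP and 2 input libraries for each protein. The labels do not say whether the 2 replicates came from separate cultures, so the spread between them may be technical.

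For each protein the authors listed windows of at most 100 nt on GRCh38 that were enriched in both replicates. The lists held 65772 entries, which were 57816 distinct windows in 6652 genes. EIF2B5 had 45824 windows in 5790 genes, EIF3J had 9121 in 2438, RPL29 had 4959 in 2114, RPL35A had 2093 in 1104, RPS19 had 1598 in 442, EIF2D had 1175 in 638, EIF2S2 had 479 in 352, RPS14 had 289 in 258 and RPS3A had 234 in 201. The total depth of each library is unknown, because reads are counted only inside called windows and listed repeat elements. Summed over the 2 libraries, IP reads in called windows ranged from 13349 for RPS14 to 1422496 for EIF2B5, and input reads from 7268 for RPS19 to 434431 for RPL29. Listed repeat elements ordered the proteins differently, with IP reads from 38940 for RPS14 to 19182198 for RPL35A, and 351535 for EIF2B5. The median window held 1 input read for RPS19, 2 for EIF2B5 and RPS14, 3 for EIF3J and 22 to 23 for EIF2S2 and RPS3A. The log2 odds ratio and the q-value of each window are the authors' own. They are used here to describe, rank or filter windows, and a range such as 7.06 to 7.29 gives the lower and the higher of the 2 replicates.

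The first question was which parts of transcripts each protein contacted. EIF2B5 and RPL29 windows lay mainly in coding sequence, with 64.9% (95% Wilson interval 64.5 to 65.4) and 71.6% (70.4 to 72.9) of windows whose top class was interior coding sequence. The intervals cover counting error only. EIF2D lay in 3′ untranslated regions, with 745 of 1175 windows (63.4%, interval 60.6 to 66.1). MTPN had 12 EIF2D windows and DCP2, the catalytic subunit of the decapping enzyme, had 11. EIF3J divided between introns (53.1%) and 5′ untranslated regions (19.8%), and it had 8.95 windows at start codons for each window at a stop codon, against 1.12 for EIF2B5 and 0.526 for EIF2D. EIF2S2 was on exons of small noncoding RNAs (188 of 479 windows, 39.2%). RPL35A had 30.9% of windows in interior coding sequence, 24.5% in 5′ untranslated regions and 230 of 2093 at start codons. RPS3A had 19.7% in introns, 15.8% in interior coding sequence, 15.4% in 5′ untranslated regions and 9.83% at start codons, and RPS14 had 34.9% in interior coding sequence and 33.2% in introns. RPS19 windows were almost wholly intronic, with 1527 of 1598 (95.6%), and only 2 lay in interior coding sequence.

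**Figure D1:**
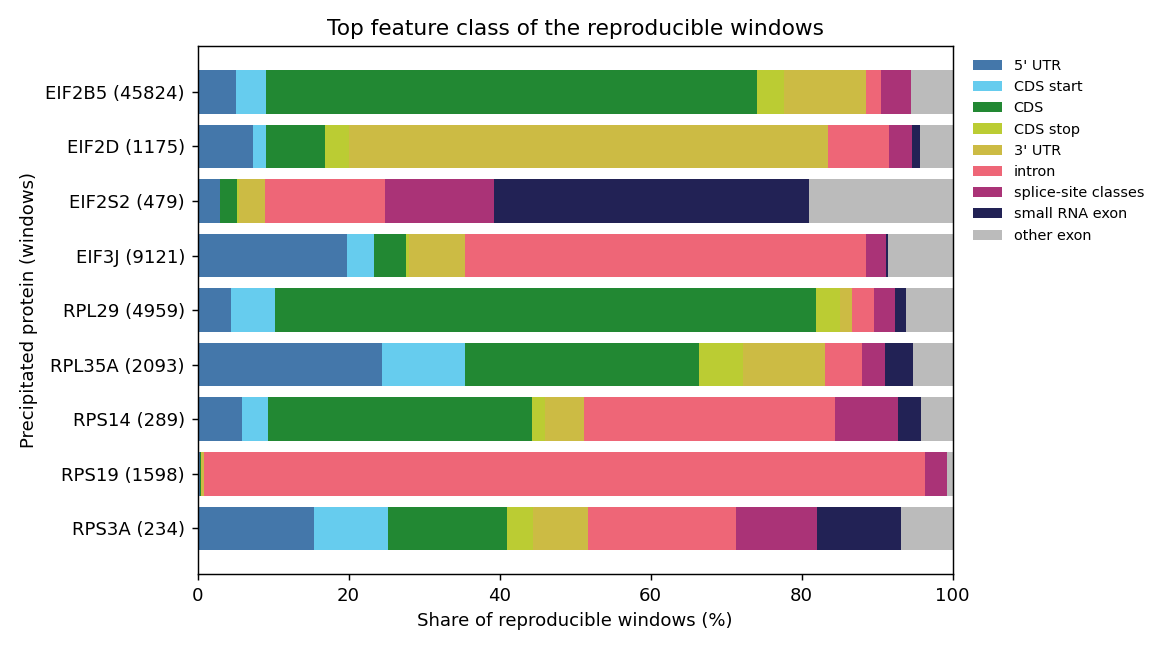
Horizontal bars show, for each precipitated protein, the percent of its reproducible windows by top feature class (x axis, 0 to 100%); the number of windows follows each name. Coding sequence fills most of the EIF2B5 (64.9%) and RPL29 (71.6%) bars, 3′ untranslated regions the EIF2D bar (63.4%) and introns the RPS19 bar (95.6%).

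Within these classes, long mRNAs supplied the most windows for EIF2B5. MACF1, a cytoskeletal crosslinker, had 170 windows, the dynein heavy chain DYNC1H1 had 152, and the ubiquitin ligases UBR4, RNF213 and HERC1 had 150, 121 and 121. RPL29 had 22 windows in NUP214 (a nuclear pore protein) and 22 in FASN (fatty acid synthase). RPL35A had 18 in TUBB and 12 each in TUBA1B and TUBA1C. Tubulin genes are near-identical, so the split of reads among them is uncertain. EIF3J had 399 windows in the long noncoding gene LINC02476, 223 in LINC00534 and 182 in CPED1. RPS19 had 60 in MGC4859, 35 in GPI and 30 in SIN3B, a transcriptional corepressor. The locus RP11-480A16.2, with 39 intronic RPS19 windows, ranked above GPI. EIF2S2 had 14 windows in CCDC200, 10 in TAF1D and 9 in SNHG1, and the latter 2 genes carry snoRNAs in their introns.

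The 4 initiation factor lists were then set against the 5 ribosomal protein lists as groups. The share of 3′ untranslated windows averaged 21.3% ± 28.2 (SD, n = 4 lists) against 5.06% ± 4.31 (n = 5), with exact permutation p = 0.135 and Benjamini-Hochberg adjusted p = 0.889. Coding sequence averaged 19.8% ± 30.2 against 30.7% ± 26.7 (exact permutation p = 0.540, adjusted p = 0.913, n = 4 and 5). None of the 16 classes passed the two-sided exact permutation test over 126 splits, either at adjusted p 0.05 or at unadjusted p 0.05. The smallest p this design can give is 0.00794, so after adjustment over 16 classes no single class could have passed, and the test does not show that the groups were alike. Permutation p-values reflect only the spread between these lists, and the Fisher's exact p-values below count windows or genes as independent and hold no spread between samples.

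Small and large subunit proteins were set side by side without a call, since the exact permutation of 3 lists against 2 cannot go below p = 0.1. Introns made up 49.5% ± 40.5 (SD, n = 3) of small subunit windows and 3.90% ± 1.38 (n = 2) of large subunit windows, a difference of 45.6 percentage points (exact permutation p = 0.2). It fell to 7.51 points in windows with at least 20 summed input reads, which left 4 RPS19 windows. Interior coding sequence was 17.0% ± 17.4 (n = 3) against 51.3% ± 28.8 (n = 2), with exact permutation p = 0.3.

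The next comparison asked which proteins shared windows. RPL35A and RPS3A, of different subunits, shared 198 windows, 84.6% of the shorter list, and the odds ratio of 481 (95% interval 285 to 811) was the highest of the 36 pairs. EIF2B5 and RPL29 shared 3911, 78.9% of the RPL29 list. Their odds ratio of 14.0 (interval 11.6 to 16.9) covers the 582 RPL29 windows in the universe tested, with 426 shared against 109 expected. EIF3J and RPL35A shared 578 (odds ratio 15.4), EIF2S2 and RPS3A 62 (odds ratio 115), and EIF2D and RPS3A 79 (odds ratio 60.9). EIF2B5 and EIF2S2 shared 42 windows. Of these, 37 lay in the universe tested, fewer than the 87.4 expected by chance (odds ratio 0.326, interval 0.231 to 0.462). This deficit did not pass in the first 500 windows (odds ratio 0.818), with at least 20 input reads (0.607) or in coding-sequence windows (0.320). RPS19 shared at most 12 windows with any other protein, the 12 being with EIF3J. Its odds ratios with RPS3A (125), RPS14 (112) and EIF2S2 (55.2) were high and passed. They rest on 8, 4 and 5 shared windows, since only 26, 22 and 26 of the 1598 RPS19 windows lay in the universes tested. The rest of the RPS19 list did not enter these tests.

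**Figure D2:**
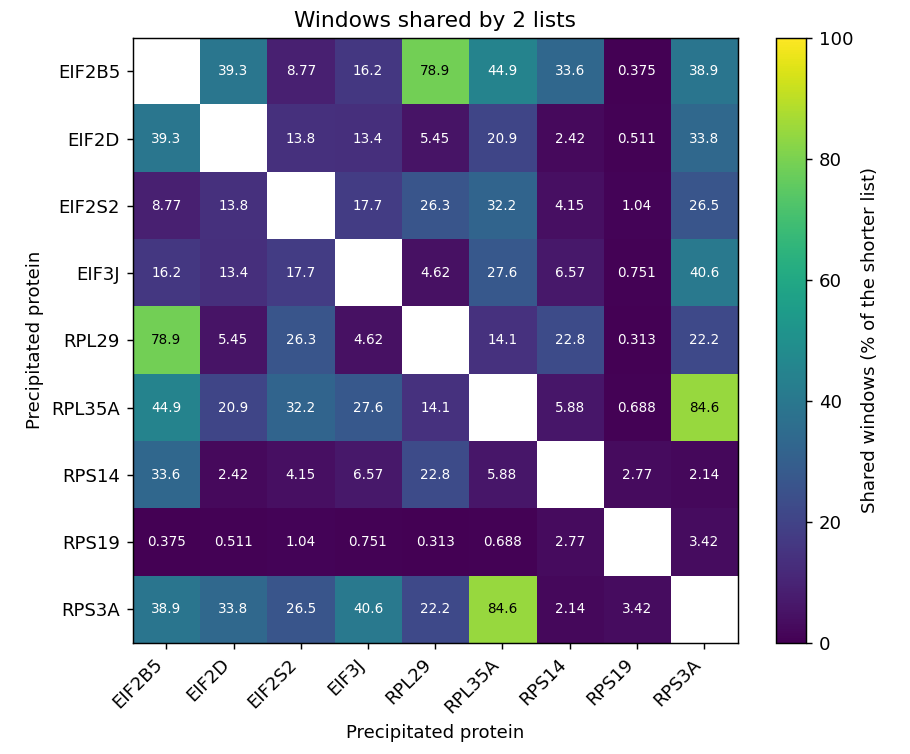
Each cell gives the windows shared by the proteins on its row and column as a percent of the shorter of their lists (colour scale 0 to 100%). The highest values are RPL35A with RPS3A (84.6%) and EIF2B5 with RPL29 (78.9%), and the RPS19 row stays at or below 3.42%.

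By Fisher's exact test (two-sided) among windows called for the other 7 proteins, 33 of the 36 pairs shared more windows than chance and 1 shared fewer at adjusted p 0.05. The adjusted p was 5.85e-249 for RPL35A with RPS3A, 9.33e-190 for EIF2B5 with RPL29 and 2.89e-12 for EIF2B5 with EIF2S2. EIF2B5 with EIF3J (odds ratio 1.09, Fisher's exact adjusted p = 0.227) and EIF2B5 with RPS19 (odds ratio 0.379, adjusted p = 0.0559) did not pass. The universe was not matched for expression, which was not measured here. It held 9722 to 18003 windows for pairs with EIF2B5 and 48974 to 57635 for the others, mostly EIF2B5 windows. Windows called for EIF2B5 alone raise the odds ratios of those other pairs by construction. Odds ratios of pairs with and without EIF2B5 are therefore not comparable, and the pairs not in excess all included EIF2B5. With a universe of windows called for any of the 9 proteins, where each list helps to define the universe, 14 pairs shared more and 16 fewer, and the EIF2B5 and RPL29 odds ratio was 0.974. The RPL35A and RPS3A pair passed under every alternative run.

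Most windows (51112, or 88.4%) were called for 1 protein. The EIF2B5 list, with 45824 windows, weighs heavily in this share, so it does not describe how specific the other lists were. Of the RPS3A windows, 84.6% were also called for RPL35A, and of the RPL29 windows 78.9% for EIF2B5. The window called for most proteins lay in the 5′ untranslated region of RPS20, a small subunit ribosomal protein mRNA (chromosome 8, 56074447 to 56074510, minus strand), and was listed for 8, all but RPS14. A window in the 3′ untranslated region of TMEM107 (chromosome 17, 8173588 to 8173674, minus strand) was called for 7. It adjoins a listed window (8173521 to 8173587) of SNORD118, the U8 small nucleolar RNA. A coding window of RPL23A (chromosome 17, 28720705 to 28720797, plus strand) and one of its pseudogene RPL23AP42 were also called for 7, and these share reads, so their separate values are uncertain. RPL24, a large subunit mRNA, had a 5′ untranslated window (chromosome 3, 101686677 to 101686718, minus strand) called for 7, and so had CTD-2643I7.4, an intronic window on chromosome 11 (5249858 to 5249954, minus strand). CHD6, a chromatin remodeller, had an intronic window (chromosome 20, 41568047 to 41568146, minus strand) called for 6 proteins. AC084082.3 and CMB9-60A24.1 had the remaining 3 of the first 10.

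Several of the highest windows, those of BTBD2, CHD6, PRTFDC1 and MYO9B in the lists given here, had 0 to 3 input reads. EIF3J was enriched in an intron of BTBD2 (chromosome 19, 1998553 to 1998650, minus strand) by 10.34 to 13.14 log2 units, with 8590 IP reads over 1 input read, and the same window led for EIF2D (9.33 to 10.85) and EIF2B5 (7.06 to 7.29). CHD6 led for EIF2S2 (9.88 to 11.42). An intronic window of PRTFDC1 (chromosome 10, 24889243 to 24889342, minus strand) was among the 5 strongest for RPL29 (7.61 to 7.64), RPL35A (9.49 to 12.09), RPS19 (8.67 to 9.14) and RPS3A (7.36 to 13.23). MYO9B, an unconventional myosin, held an intronic window (chromosome 19, 17082471 to 17082570, plus strand) at 9.28 to 11.67 for RPL35A and 7.29 to 12.72 for RPS3A. RPS14 was highest in coding windows of ANKRD10 (8.76 to 9.30), RPL23A (8.09 to 8.28) and PNN, a splicing-related protein (7.85 to 8.53). MAN1B1 was highest for RPS19 (8.90 to 9.74, 311 IP reads over 1 input read). Where the input was this low, the size of an odds ratio is uncertain beyond the replicate range, while RPL23A had 28 input reads for RPS14. For RPL29 the median window held 12 IP and 9 input reads at a median midpoint of 3.60, and the library totals behind this ratio are not given.

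Replicates differed by a median over windows of 0.41 log2 units for EIF2D, 0.59 for RPL29, 0.62 for RPL35A, 0.69 for RPS3A, 0.78 for EIF3J, 0.81 for RPS19, 0.85 for EIF2B5, 1.05 for RPS14 and 1.19 for EIF2S2. The median enrichment of a window (midpoint of the replicates) was 2.20 for EIF2D and 2.71 for RPL35A, and 5.08 and 5.64 for RPS19 and RPS14.

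Fixed gene lists were then tested for each protein. Among the 6652 genes with a window for any protein, genes of the translation machinery recurred. Of the 47 large subunit ribosomal protein genes in this universe, 38 had a window for RPL29, 36 for RPL35A, 32 for EIF3J, 31 for EIF2D, 12 for EIF2S2 and 5 for RPS3A, each over-represented. Of the 32 small subunit genes, 28 had a window for RPL35A, 23 for RPL29, 21 for EIF2D, 20 for EIF3J, 9 for RPS3A and 7 for EIF2S2. A window counted for every gene named on it, and many EIF2S2 windows in these genes lay on small RNA exons, as given below. EIF3J had 28 of its 39 windows on large subunit mRNAs in 5′ untranslated regions (71.8%) and EIF2D 26 of 52, while RPL29 had 52 of 109 in interior coding sequence (47.7%, below its 71.6% over all windows). Differences between these shares were not tested. EIF2D was enriched at the 5′ untranslated region of RPL37 (2.92 to 3.27) and RPS12 (2.85 to 3.05), and RPL35A at that of its own mRNA, RPL35A (chromosome 3, 197950190 to 197950244, plus strand; 5.62 to 6.45). The Fisher's exact adjusted p for large subunit genes was 4.10e-18 for RPL35A, 1.71e-19 for EIF2D and 5.52e-11 for RPL29.

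EIF2D stood on mitochondrial transcripts. All 13 mitochondrially encoded genes in the universe had an EIF2D window, against 1.25 expected (Fisher's exact adjusted p = 8.51e-13), including MT-ND3 (2.63 to 2.89) and MT-ND5 (2.49 to 2.89), subunits of respiratory complex I. RPL35A covered 11 of the 13, EIF3J 9 (Fisher's exact adjusted p = 0.0507, and 0.0399 adjusted over the list alone) and RPS3A 7. EIF2B5 covered 6, fewer than chance (Fisher's exact adjusted p = 0.00198), but its odds ratio of 0.128 turned to 2.78 with at least 20 input reads. EIF2D was also over-represented on globin and haem genes (8 of 17, with HBA2 at 2.31 to 2.44), nuclear oxidative phosphorylation genes (10 of 43, turning to odds ratios of 0.682 in the first 500 windows and 0.599 with at least 20 input reads), cytoskeletal genes (13 of 23) and SR proteins and hnRNPs (15 of 33). Of its 28 windows in SR protein and hnRNP genes, 26 (92.9%) were in 3′ untranslated regions, such as HNRNPA0 (3.51 to 3.98). None of the 53 mitochondrial ribosomal protein genes had an EIF2D window, against 5.08 expected (Fisher's exact adjusted p = 0.0246).

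EIF2S2 windows lay on small noncoding RNA genes and on genes that host snoRNAs. Of 161 small noncoding RNA genes, 122 had an EIF2S2 window against 8.52 expected (odds ratio 84.2, Fisher's exact adjusted p = 4.04e-127), and of 26 snoRNA host genes 24 had one (adjusted p = 1.92e-27). SNORD118 was enriched by 6.36 to 7.25 log2 units (12697 IP and 409 input reads), SNORD124 by 6.88 to 8.06 and SNORD8 by 6.42 to 6.83. Among host genes, ZFAS1 reached 5.97 to 6.52 and SNHG29 5.44 to 7.56. Ribosomal protein and translation factor genes (9 of 47) were over-represented too. Their windows were of a splice-site class in RPL7A (6.92 to 7.65) and of the mRNA exon class, which is separate from coding sequence, in RPL4 (5.95 to 6.91) and EIF4A1 (5.67 to 5.97). Of the 35 EIF2S2 windows in large subunit genes, 14 were of the mRNA exon class and 11 on small RNA exons. Of the 20 in small subunit genes, 10 were on small RNA exons, 2 of the mRNA exon class and 0 in interior coding sequence. The ribosomal protein calls of EIF2S2 therefore overlap in part with its small RNA result. Cytoskeletal genes had 6 of 23 (adjusted p = 0.00348 by Fisher's exact test), which turned to odds ratios of 0.976 with q at most 0.05 and 0.353 with at least 20 input reads. Small subunit genes turned to 0.688 in the latter.

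EIF3J windows lay on 39 of 43 nuclear oxidative phosphorylation genes (Fisher's exact adjusted p = 2.66e-12) and 42 of 48 replication-dependent histone genes (adjusted p = 4.85e-12). On the former, 31 of 60 windows were in 5′ untranslated regions and 25 at start codons. COX7B, a cytochrome oxidase subunit, was enriched by 3.68 to 3.90 and NDUFB10 by 3.02 to 3.56. Chaperone genes (24 of 30, with TCP1 at 2.97 to 3.20 and HSPA4 at 2.97 to 3.13), glycolysis genes (12 of 16, with TPI1 at 3.21 to 3.95), SR proteins and hnRNPs (28 of 33) and cytoskeletal genes (15 of 23) were over-represented. The excess of small subunit genes for EIF3J turned to an odds ratio of 0.403 in the first 500 windows. Small noncoding RNA genes were under-represented (12 of 161 against 59.0 expected, Fisher's exact adjusted p = 1.41e-16). EIF2S2 had a window in 122 of these 161 genes, so its list helped to bring them into the universe. Genes brought in by EIF2S2 alone lower the share of every other list by construction, so this deficit does not by itself show avoidance.

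RPL35A was over-represented on 18 of the 20 lists tested, the exceptions being aminoacyl-tRNA synthetases and mitochondrial ribosomal proteins. Replication-dependent histones led, with 42 of 48 (Fisher's exact adjusted p = 1.78e-25), H4C11 at 5.28 to 5.85 and H4C3 at 5.15 to 5.90, although H4 genes share much of their sequence. Nuclear oxidative phosphorylation (31 of 43), globin and haem genes (13 of 17, with HBA1 at 4.49 to 4.62, a near copy of HBA2), glycolysis (13 of 16, with PGK1 at 4.94 to 4.99), cytoskeleton (16 of 23), chaperones (19 of 30), SR proteins and hnRNPs (20 of 33), translation factors (19 of 47), snoRNA hosts (16 of 26), small noncoding RNAs (52 of 161), proteasome (11 of 30, with PSMA5 at 4.23 to 5.02), cell cycle (12 of 27, with PCNA at 4.40 to 5.50) and selenoproteins (6 of 10) followed. SELENOS, a selenoprotein of the endoplasmic reticulum, carried a 3′ untranslated window at 6.86 to 7.83 with 256 IP reads over 1 input read. RPL29 was over-represented on 12 lists, led by SR proteins and hnRNPs (30 of 33, Fisher's exact adjusted p = 2.38e-11) and the large subunit genes given above, and including translation factors (34 of 47), with HNRNPM at 5.75 to 5.81 and EIF4A2 at 5.49 to 5.68. RPS3A was over-represented on 8, including histones (15 of 48, with H4C3 at 4.38 to 4.52), cytoskeleton (6 of 23) and globin and haem genes (6 of 17). Small noncoding RNAs were also among the 8 (15 of 161, with VTRNA2-1 at 3.05 to 4.03). RPS14 passed for translation factors (8 of 47, Fisher's exact adjusted p = 0.00155, with EIF4A2 at 6.48 to 7.05) and cell cycle genes (4 of 27, adjusted p = 0.0494). The latter did not pass when adjusted over the list alone (p = 0.192 by Fisher's exact test) and turned to an odds ratio of 0.532 with q at most 0.05. RPS19 passed for none in excess, and for small noncoding RNAs in deficit (1 of 161 against 10.7 expected, odds ratio 0.128, Fisher's exact adjusted p = 0.00128). That deficit changed direction with at least 20 input reads, which left 4 RPS19 windows. As for EIF3J, it follows in part from the EIF2S2 genes in the universe. In the first 500 windows the excess turned to a deficit for RPL29 on glycolysis, cytoskeletal and histone genes, for RPL35A on translation factors, SR proteins and hnRNPs, snoRNA hosts and small noncoding RNAs, and for RPS3A on small noncoding RNAs (odds ratios 0.149 to 0.923). With at least 20 input reads it did so for RPL29 on chaperone, glycolysis, cell cycle and histone genes, for RPL35A on oxidative phosphorylation, cell cycle and small noncoding RNA genes, and for RPS3A on large subunit genes (odds ratios 0.422 to 0.976).

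EIF2B5 had a window in 87.0% of the universe, so few lists could stand out. All 32 small subunit genes, all 33 SR protein and hnRNP genes and 47 of 48 histone genes had one (each Fisher's exact adjusted p = 0.0449; histones turned to an odds ratio of 0.665 with at least 20 input reads), while small noncoding RNAs (13 of 161, adjusted p = 3.39e-117) and snoRNA hosts (16 of 26, adjusted p = 0.00341) were under-represented. In all, 64 of 180 combinations of list and protein were over-represented and 6 under-represented. With p adjusted over the list alone, taken as the 20 lists of a single protein, the totals were again 64 and 6, but EIF2B5 had 0 in excess and EIF3J had 10. Over-represented combinations numbered 41 with a larger q-value of at most 0.05, 26 in the first 500 windows of each list and 19 in windows with at least 20 input reads. Without the EIF2B5 list there were 43, and 18 of the calls for other proteins no longer passed, among them ribosomal protein, glycolysis and cytoskeletal genes for EIF3J, oxidative phosphorylation for EIF2D, large subunit genes for RPS3A, cell cycle genes for RPL35A and RPS14, and the mRNAs of the precipitated proteins for RPL29 and RPL35A. For RPL29 these also included globin and haem, chaperone, glycolysis, cell cycle, cytoskeletal, histone and snoRNA host genes, and for RPL35A small noncoding RNAs. The gene universe was not matched for expression either. EIF2S2 had a window in 122 of the 161 small noncoding RNA genes and 24 of the 26 snoRNA hosts. Those it brought into the universe alone add to the EIF2B5 deficits on these 2 lists by construction.

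Of the mRNAs with regulatory upstream reading frames that respond to stress, 16 of the 20 fixed were in the universe. RPL35A was over-represented on them (7 of 16, Fisher's exact adjusted p = 0.0279), though the odds ratio of 3.98 turned to 0.264 in the first 500 windows and 0.581 with at least 20 input reads, with EPRS1 at 3.55 to 4.87 and AZIN1 at 2.82 to 4.80. EIF3J had 8 of 16, among them ODC1, the first enzyme of polyamine synthesis, whose 5′ untranslated window (chromosome 2, 10448259 to 10448327, minus strand) was at 2.70 to 3.62, RPL29 had 8 and EIF2B5 had all 16, none of which passed. For ATF4, the stress-response transcription factor, EIF2B5 was enriched in the 5′ untranslated region (4.93 to 5.64), RPL29 at the start codon (3.49 to 3.78) and RPL35A in the 5′ untranslated region (2.26 to 2.36). ATF4 was also among the genes with an EIF3J window. DDIT3 had windows for EIF2B5 (4.32 to 4.47) and RPL29 (3.33 to 4.32). The 9 mRNAs of the precipitated proteins themselves were over-represented for RPL29 (7 of 9, Fisher's exact adjusted p = 0.0190) and RPL35A (5 of 9, adjusted p = 0.0254). EIF2S2 mRNA was enriched for EIF2B5 (6.19 to 6.39) and RPL29 (6.03 to 7.28), and EIF2B5 contacted its own mRNA at 4.16 to 4.82.

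The repeat element tables covered RNAs encoded by many copies, and these values are from the authors' deposited table for each protein. Initiator tRNA, which carries the first methionine, was the highest tRNA entry by the lower replicate in the authors' deposited table for EIF2D (6.83 to 7.37), EIF2S2 (7.44 to 10.33) and EIF2B5 (4.19 to 5.96). By the higher replicate a lysine tRNA (10.75) passed it in the authors' deposited table for EIF2S2. Ranked by the lower replicate in the authors' deposited table for RPL35A, it was the second tRNA (6.64 to 7.92), behind a lysine tRNA (6.76 to 6.95), and for EIF3J and RPS3A it ranked 6 among 40 and 38 tRNA entries. Its midpoint exceeded the median of the other listed tRNAs by 3.87 log2 units for EIF2D, 3.85 for EIF2S2, 3.65 for RPL35A and 3.60 for EIF2B5, against 0.77 for EIF3J and 0.76 for RPS3A, all from the authors' deposited table. Only tRNAs listed as enriched for a protein enter its median, so the baselines differ and these gaps are not strictly comparable between proteins. In all, the authors' deposited table listed 55 tRNA entries for RPL35A, 41 for EIF2D, 40 for EIF3J, 38 for RPS3A, 36 for EIF2S2, 15 for EIF2B5, 1 for RPS19 and 0 for RPL29 and RPS14.

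**Figure D3:**
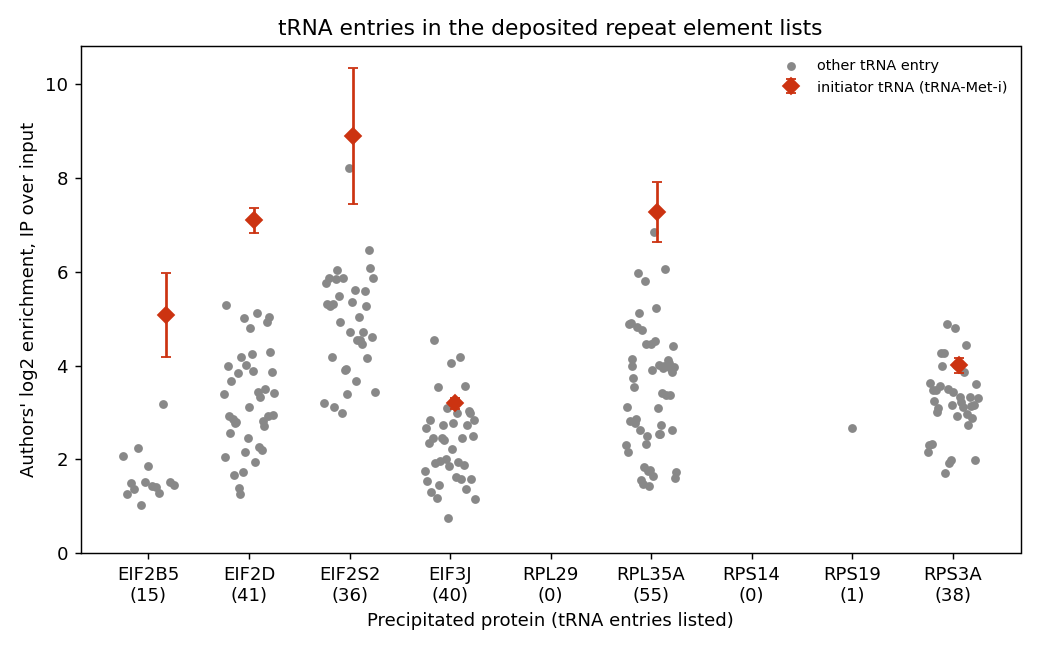
Points are tRNA entries of the authors' deposited table for each precipitated protein (x axis, with the number of entries) by log2 enrichment of IP over input, midpoint of the 2 replicates (y axis); the diamond is initiator tRNA with bars from the lower to the higher replicate. Initiator tRNA stands 3.60 to 3.87 log2 units above the median of the other listed tRNAs for EIF2B5, EIF2D, EIF2S2 and RPL35A, and 0.76 to 0.77 above for EIF3J and RPS3A.

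Small subunit ribosomal RNA was enriched in the authors' deposited table for RPL35A (2.51 to 3.58), EIF2D (1.99 to 2.14), RPS3A (1.89 to 2.94) and RPL29 (1.33 to 1.40), and large subunit ribosomal RNA only for RPL29 (1.21 to 1.28). The 7SK RNA, a regulator of transcription elongation, was listed in the authors' deposited table for EIF2B5 (1.06 to 2.14) and RPL29 (1.56 to 1.64), and 7SL for none. For EIF2S2 the authors' deposited table gave the small nucleolar RNAs U8 (6.30 to 7.08) and U3 (4.99 to 5.75), and for RPL29 the same 2 RNAs at 3.97 to 4.31 and 3.59 to 3.75. Among L1 elements, a family of retrotransposons, the authors' deposited table listed 118 sense entries for EIF3J and 52 for EIF2B5 and no antisense entry for either. For RPS19 the authors' deposited table listed 36 antisense and 0 sense L1 entries, led by L1P2 (4.28 to 5.39) and L1PA2 (4.19 to 5.01), and for EIF2D 13 antisense entries with a median lower replicate of 1.03. GA-rich simple repeats led for EIF2B5 in the authors' deposited table, with (AGATGA)n at 5.63 to 6.73, and the same repeat was second for RPL29 (3.84 to 4.54). For RPS14 the authors' deposited table held 6 entries, headed by MamGypLTR1b, MER102c and LTR9, elements with long terminal repeats or of DNA transposon origin, at 4.05 to 4.62, 3.86 to 4.12 and 3.55 to 4.08.

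Base composition was compared within transcript parts, since these differ in GC content. In interior coding sequence the median GC content per list averaged 45.9% ± 1.64 (SD, n = 3 lists) for initiation factors and 53.1% ± 3.82 (n = 4) for ribosomal proteins (exact permutation p = 0.0571, adjusted p = 0.150). The lists ranged from 44.2% for EIF3J to 57.6% for RPL35A. In 3′ untranslated regions the averages were 38.4% ± 3.50 (n = 3) and 50.7% ± 2.55 (n = 2), with the smallest p this design allows (exact permutation p = 0.1, adjusted p = 0.150). In 5′ untranslated regions they were 61.0% ± 4.25 (n = 3) and 59.8% ± 4.99 (n = 3), with exact permutation p = 1. The smallest p the exact permutation test can give is 0.0286 for coding sequence and 0.1 for each untranslated region, so no class could have passed at adjusted p 0.05 and the outcome does not show that the groups were alike.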

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

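All tests in this part were chosen after the values they concern had been seen, and the patterns are hypotheses from the same data. Lists that stood apart from others of their class were sought over 30 measures with Dixon's test for a single extreme value. This gave 13 values in 55 groups of lists. With normal values in independent groups, chance alone would give about 1 in 20 groups, or 2.75. Neither condition holds, since shares of one list depend on each other and some counts were mostly 0. Several of the 13 were shares of the same EIF2S2 list, so 13 beside 2.75 does not measure an excess over chance.

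Some windows followed the class of the protein. Of 230 windows called for 4 or more proteins, 7 were called in a single class: BTBD2, TTC3 and WNK1 for the 4 initiation factors, PRTFDC1, MYO9B and E2F2 for the 5 ribosomal proteins, and ADGRL1 for 4 ribosomal proteins. Chance could not be excluded, since 37 of the 126 splits of the 9 lists into 4 and 5 gave as many, and the highest other split gave 81 (EIF2S2, RPS14, RPS19 and RPS3A against the rest). That split sets the 4 longest lists on the same side, and the count does not allow for list length, so a structure of the lists by length was not separated from one by protein class. Few reads in the input stay open as a source: the median per window and list was 1 input read beside 180 IP reads (quartiles 42.5 and 976), and windows called for many proteins have many IP reads by selection. Input differed between the 7 windows, from 2 reads summed over the lists for BTBD2 to 112 for PRTFDC1 and 124 for E2F2. Libraries of one class prepared together could give the same 7 windows, and the labels hold no preparation batch that would separate this from a contact of the proteins.

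RPS19 stood apart from the other ribosomal proteins in the authors' deposited table, with 36 antisense L1 entries where the others had 0 to 5. Its share of intronic windows (95.6%, 1527 windows in 413 genes) was the highest of the 9 lists but did not pass Dixon's test. Carry-over of genomic DNA would give both strands alike, and 100% of its L1 entries were antisense (36 of 36). Related entries share reads, and counted as 7 name stems, all antisense, the exact 95% lower bound was 59.0%. This lies above an even split. The bound treats the stems as independent, though they are related elements called from the same libraries, so it cannot decide about carry-over. It also fell short of a higher cut-off, chosen after the values were seen, so carry-over stays open. A few genes holding most windows is argued against, since the 10 genes with most held 19.2% of the intronic windows. Whether the intronic windows lie in antisense L1 copies was not tested, as no repeat positions were at hand.

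Many tRNA entries appeared in the authors' deposited table for 6 of the 9 proteins. The number of windows called is argued against as the cause, since 3 lists with over 1000 windows had fewer tRNA entries than a list with under 500, as with RPL29 (4959 windows, 0 entries) and RPS3A (234 windows, 38 entries). Protein class alone is argued against as well: RPL35A had 55 entries, above the 41 of EIF2D, the highest among initiation factors (means 33.0 ± 12.2 SD, n = 4, and 18.8 ± 26.0, n = 5, exact permutation p = 0.349). An excess of initiator tRNA in initiation factors alone is argued against by RPL35A at 3.65 log2 units over the other listed tRNAs and EIF3J at 0.77. Differences in library preparation between the proteins were not tested, since the labels give none, and so stay open.

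Other values apart from their class were as follows, without a test of cause. EIF2B5 had 64.9% of windows in coding sequence (other initiation factors 2.30 to 7.74%), 1.42% in the class SS3_ADJ (0.170 to 0.351%) and 85 simple repeat entries in the authors' deposited table (9 to 21). EIF2D had 63.4% in 3′ untranslated regions (3.55 to 10.9%) and 13 antisense L1 entries in the authors' deposited table (0). EIF2S2 had 39.2% on small RNA exons (0.0567 to 0.936%), 11.9% in the mRNA exon class (0.851 to 2.67%), 4.18% in SS5_ADJ (0.384 to 0.834%), 2.71% in SS3_PROX (0.476 to 0.800%), 3.76% in SSB_PROX (0.121 to 0.358%) and 2.51% in primary microRNAs (0.0175 to 0.170%). RPS3A had 0.855% in primary microRNAs (other ribosomal proteins 0 to 0.143%).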

How the results depend on the processing

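Overlap in coding-sequence windows alone and the runs without the EIF2B5 list were chosen after the results were seen. The cause of the changes below was not tested, except where it follows by construction. No paired analysis was possible because the deposited columns pool the replicates and carry no replicate numbers, and for the same reason no replicate could be left out. A q-value of at most 0.05 removed no repeat element and so says nothing about them, and overlap of at least 1 nt moved nothing, as the windows of the lists tile without partial overlap. The adjusted test of initiation factors against ribosomal proteins says nothing about stability, since no single class could pass it with 9 or 8 lists. The difference in 5′ untranslated share (-1.30 percentage points) became 1.77 with q at most 0.05, 4.22 in the first 500 windows, 7.53 with at least 20 input reads, 9.02 by genes, and 0.657, 2.29 and 0.0241 without EIF2S2, RPL35A or RPS3A. That in introns (-11.5) became 4.60 without RPS19. The small minus large subunit difference in introns (45.6) became 7.51 with at least 20 input reads. The GC difference in 5′ untranslated windows (1.17) became -1.42 with q at most 0.05 and -3.28 in the first 500 windows. Of 36 pairs, 33 shared more and 1 fewer. These became 21 and 0 in the first 500 windows, 20 and 0 with at least 20 input reads, 14 and 16 with a universe of any of the 9 lists (by construction, since each list then adds windows the other lacks) and 20 and 2 in coding-sequence windows. Pairs sharing fewer were 2 with a lower-replicate log2 of at least 1, 2 by genes, and 0 without the EIF2B5 list. The odds ratio of EIF2B5 with RPS19 (0.379) was 1.12 in the first 500 windows and 1.38 by genes. With a universe of any of the 9 lists, EIF2B5 with RPL29 (14.0) was 0.974, EIF2B5 with EIF3J (1.09) 0.0190 and EIF2D with EIF3J (7.30) 0.822. EIF2B5 with EIF3J was 0.340 in coding-sequence windows. Over-represented combinations of gene list and protein (64) numbered 41 with q at most 0.05, 26 in the first 500 windows, 19 with at least 20 input reads and 43 without the EIF2B5 list, where 18 calls for other proteins no longer passed, and under-represented ones (6) were 3 among protein-coding genes. Odds ratios of called lists that changed direction were, with q at most 0.05, cytoskeleton for EIF2S2 0.976 and cell cycle for RPS14 0.532. In the first 500 windows they were oxidative phosphorylation for EIF2D 0.682, small subunit genes for EIF3J 0.403, for RPL29 glycolysis 0.149, cytoskeleton 0.815 and histones 0.495, for RPL35A translation factors 0.923, stress response 0.264, SR proteins and hnRNPs 0.685, snoRNA hosts 0.556 and small noncoding RNAs 0.741, and for RPS3A small noncoding RNAs 0.784. With at least 20 input reads they were for EIF2B5 mitochondrially encoded genes 2.78 and histones 0.665, for EIF2D oxidative phosphorylation 0.599, for EIF2S2 small subunit genes 0.688 and cytoskeleton 0.353, for RPL29 chaperones 0.643, glycolysis 0.422, cell cycle 0.655 and histones 0.930, for RPL35A stress response 0.581, oxidative phosphorylation 0.972, cell cycle 0.491 and small noncoding RNAs 0.976, for RPS19 small noncoding RNAs 2.49 and for RPS3A large subunit genes 0.707. Of the 414 named windows, 320 passed q at most 0.05 and 92 had at least 20 input reads.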

Other observations

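Further genes with many windows or high enrichment were these. EIF2D, besides its 3′ untranslated windows, had 34 windows in F11-AS1 and 14 in NORAD, a cytoplasmic long noncoding RNA that binds Pumilio proteins. RPL35A had 11 windows in RACK1, a small subunit scaffold protein mRNA. RPS3A had 4 windows each in Y RNA genes and in RPS3, and RPS14 had 3 each in PRKCB and NDUFV3. For EIF2D, windows of NEU3 (chromosome 11, 74997319 to 74997418, plus strand, intron; 8.13 to 9.06) and FBXL13 (7.77 to 8.07) were among the 5 highest, and NEU3 was also high for EIF2S2 (8.91 to 10.17). PTBP2, a neuronal splicing regulator, had an intronic window for EIF2D (6.46 to 6.81) and EIF3J (7.27 to 7.89).

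Of the fixed lists, aminoacyl-tRNA synthetases passed for none of the 9 proteins at p adjusted over all 180 tests, and for RPL29 (11 of 20) at p adjusted over the list alone (0.0480, Fisher's exact test). The mitochondrial ribosomal protein list passed for EIF2D alone, in deficit. Markers of lymphoid, stromal and epithelial cells had 3 genes of 22 in the universe, EPCAM, KRT18 and KRT8, too few to test. Nuclear long noncoding RNAs had 4 of 5 and were not tested either.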
